A study of Mus musculus with 4 samples.

How the data were processed

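The series holds 4 arrays of macrophages from mouse livers, from 10 wild-type (WT) and 10 mPGES-1 knockout (KO) mice, 48 h after reperfusion. Strain was C57/BL6 per the labels. Per the labels, RNA was isolated with TRIzol, and biotin-labelled single-stranded DNA was made from 5 ng of total RNA with the WT Pico kit and hybridised to Affymetrix Mouse Gene 2.0 ST arrays. The small RNA input means strong amplification before hybridisation. Each array holds 1 combination of genotype and Ly6C gate, so there is 1 array per group, and whether RNA of several mice was pooled for it is not given in the sources used here. For arrays, their number limits the precision. The p-values given measure only the spread between these arrays.

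The authors deposited gene-level log2 values made with the RMA method in Expression Console, per the labels; the submitters' processing notes also name RMA. RMA as generally known corrects background, quantile normalises arrays and summarises probes into 1 value per probe set. The log2 scale was read from the range of the values. Software versions, the array annotation build and the number of mice behind each array are not given in the sources used here. The medians of the deposited values over all 41345 probe sets were 4.03 for WT Ly6C-hi, 4.10 for WT Ly6C-low, 4.20 for labelled KO Ly6C-hi and 4.03 for labelled KO Ly6C-low, with SDs of 1.83, 1.75, 1.69 and 1.79.

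Of 41345 probe sets, 23521 had 1 gene symbol in the platform annotation, 1814 had several and 16010 had none listed. Only probe sets with 1 symbol were used. Of these, 23328 matched the RefSeq gene table (GRCm38.p6) by Entrez ID, which gave the current symbol, and 193 did not match and kept the symbol of the annotation. They stood for 22180 genes, 1082 of them with several probe sets, for which the probe set with the highest mean over the 4 arrays was taken. A level of at least 6 on the log2 scale in at least 1 array was reached by 5306 genes. No coordinates were used except the order of genes around Ptges in that table.

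Pairwise differences were computed as Ly6C-hi minus Ly6C-low in WT and under the KO label, and as labelled KO minus WT in each gate. Genes were counted at 2-fold or more among those with a log2 level of at least 6 in the brighter array. With 1 array per group these differences have no p-value. The difference of differences was counted over the 5306 genes. The gate and genotype effects were fitted with limma 3.58.1 in R 4.3.3 as an additive model of both factors over these genes, with eBayes and a trend on level, and Benjamini-Hochberg adjusted p under 0.05. This leaves 1 residual degree of freedom per gene and takes the genotype by gate difference as noise, with its median over genes of -0.67 as deposited. The estimated prior degrees of freedom were infinite for the deposited values at the log2 floor of 6. They were 6.74 when centred, 12.46 with quantile normalisation, 10.16 with lowess and 7.07 with no floor. In the fit with infinite prior degrees of freedom, the SE of a gene was set by the trend at its level and not by its own residual. A gene with a large difference in a single gate can therefore pass the test of the average. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.

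Gene lists covered 17 functions (inflammatory monocyte, non-classical monocyte, Kupffer cell, repair macrophage, inflammatory mediators, prostanoid and eicosanoid, interferon response, class II presentation, complement and efferocytosis, lipid and cholesterol handling, iron and heme, tissue remodelling, growth factors, cell cycle, hypoxia and glycolysis, oxidative burst and granule, immediate early and stress) and 13 cell types the gate could hold (hepatocyte, sinusoidal endothelial, stellate and fibroblast, cholangiocyte, neutrophil, T, NK and B cell, conventional and plasmacytoid dendritic cell, erythroid, platelet and megakaryocyte, and eosinophil, basophil and mast cell). Members at a log2 level of at least 6 in at least 1 array were used, and lists with at least 5 of them were set against 10000 random lists of the same size matched on mean level in 20 bins. Of 84 list medians, 46 lay outside the central 95% of random lists, where 4.2 would by chance. These percentiles describe these arrays only.

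Genes named in the text follow a rule. Ptges comes first. For each pairwise comparison the 10 largest differences each way were taken among genes with 1 symbol, a log2 level of at least 6 in the brighter array and an absolute difference of at least 1, leaving out predicted, RIKEN, microRNA, snoRNA, snRNA, pseudogene, immunoglobulin and T cell receptor segment symbols. For the averaged effects and the difference of differences the 5 largest each way were taken, and for each list up to 4 members with the largest absolute difference. Further members of a list, and genes named because they passed limma or moved in both gates, were chosen after their values were seen. The groups, comparisons, tests, lists, naming rule and the alternatives below, except those named as later, were fixed before the data were examined.

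The alternatives were log2 floors of 5 and 7 and no floor; centring each array on the median gene; lowess of the difference on mean level (span 0.4); quantile normalisation; the mean or the dimmest of a gene's probe sets; a 1.5-fold threshold; eBayes without trend; the same direction past 2-fold in both pairs in place of a test; and the mean of a list's members. Quantile normalisation of list medians, protein-coding genes only, leaving out chemosensory receptor genes or the genes of the cell type lists, and limma within lists at other normalisations were chosen after seeing the data, as were 3 added lists (chemosensory receptors, ribosomal proteins and proteasome). Intervals on list medians are 95% intervals from 2000 bootstrap draws of the members and cover the spread between genes only.

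The procedure was tested on simulated arrays of 5306 genes with a noise SD of 0.36. For the gate effect, limma called 100% of 100 genes changed 4-fold and of 100 changed 16-fold, and 0.176% of 5106 unchanged genes. In a single pair, 97.0% of the 4-fold genes and 4.43% of the unchanged genes passed 2-fold. For the genotype effect, with none simulated, 0.00% of 5306 genes were called. The simulated noise had the same SD for all genes, with no shift between arrays, no trend with level and no genotype by gate difference. The measured arrays had a median difference of differences of -0.67, so these rates need not hold for them. Probe sets with several or no listed symbols were left out of the comparisons.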

Results

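Gene expression was measured in macrophages sorted from mouse livers 48 h after reperfusion, the return of blood flow after a period of ischaemia. The livers came from 10 wild-type (WT) mice and 10 mice labelled as lacking mPGES-1, the prostaglandin E synthase encoded by Ptges. The cells were divided by Ly6C, a surface protein abundant on recently recruited inflammatory monocytes, into Ly6C-hi and Ly6C-low fractions. Each of the 4 combinations of genotype and fraction was hybridised to 1 Mouse Gene 2.0 ST array. The number of genes with a log2 level of at least 6 was 4171 in WT Ly6C-hi, 3594 in WT Ly6C-low, 3066 in the array labelled KO Ly6C-hi and 4159 in the array labelled KO Ly6C-low. There was 1 array per group, so no difference between 2 arrays has a replicate check, and the number of arrays limits the precision of every value. Across genes, the spread of the difference between 2 arrays was 0.50 on the log2 scale (robust SD, from the split of the 4 arrays that follows neither genotype nor fraction). That split is the genotype by fraction difference, so this spread holds any true difference of that kind and is not replicate noise.

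Ptges was not lower in the arrays labelled KO. Its single probe set (17383712) read 5.65 in WT Ly6C-hi and 6.32 in the array labelled KO Ly6C-hi, and 5.69 in WT Ly6C-low and 6.20 in the array labelled KO Ly6C-low. The differences, 0.68 and 0.51, went against the label. Where its probes lie relative to the deleted part of the gene is not given in the sources used here, and a probe outside that part checks nothing. The genotype is therefore given below as the label of each array, and each genotype difference rests on that label. The fractions differed in Ly6c2, which encodes the Ly6C antigen: 7.70 in Ly6C-hi and 3.84 in Ly6C-low of WT, and 8.94 and 4.33 under the KO label.

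**Figure D1:**
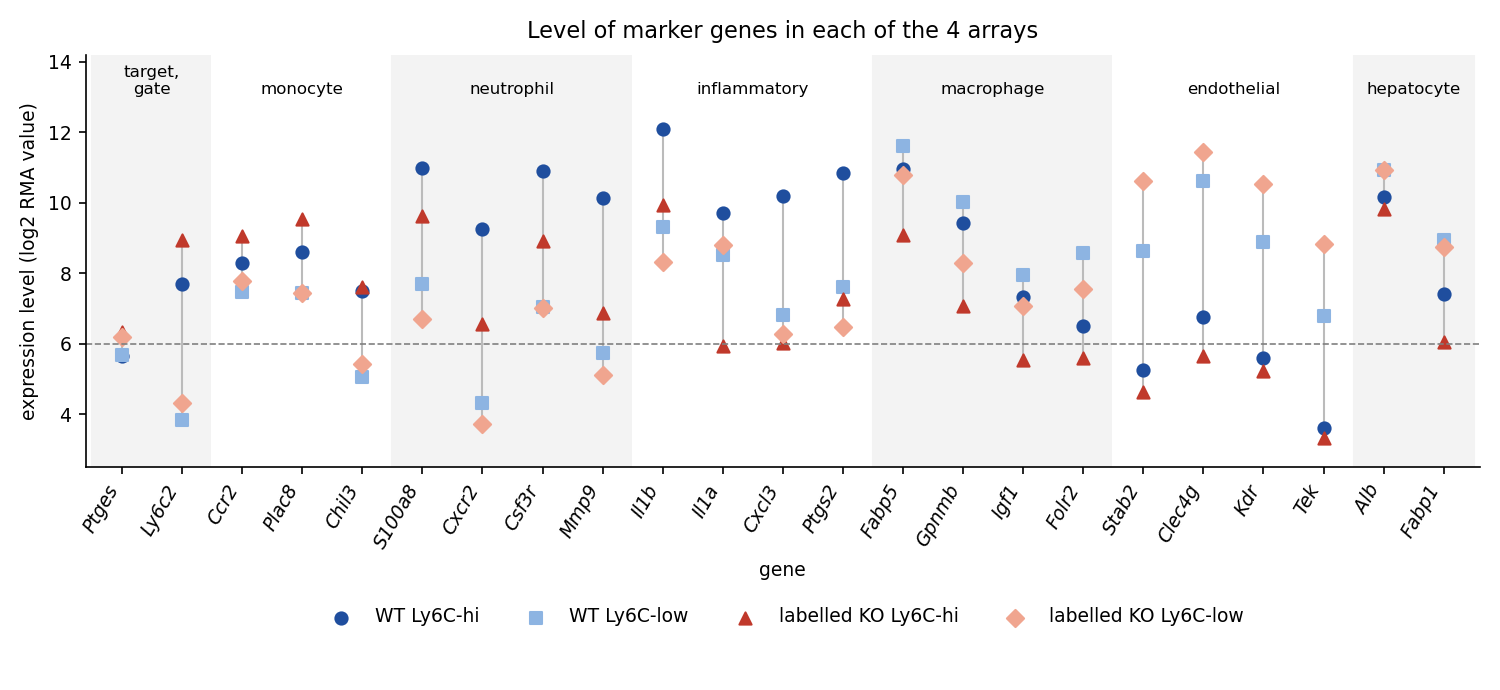
Log2 RMA level (vertical axis) of 23 genes in each of the 4 arrays, 1 point per array, grouped by targeted gene and gate marker, monocyte, neutrophil, inflammatory, macrophage, endothelial and hepatocyte genes; the dashed line is the log2 level of 6 used as a floor. Stab2 runs from 4.63 in the array labelled KO Ly6C-hi to 10.61 in the array labelled KO Ly6C-low, Il1a from 5.92 in the array labelled KO Ly6C-hi to 9.70 in WT Ly6C-hi, and Ptges stays between 5.65 and 6.32.

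Ly6C-hi cells of WT livers carried high levels of neutrophil and inflammatory transcripts relative to Ly6C-low cells. All 15 measured neutrophil markers were at least 2-fold higher in Ly6C-hi, with a median difference of 3.29. Among them were the chemokine receptor Cxcr2 (9.25 against 4.33), the decoy interleukin-1 receptor Il1r2 (11.28 against 6.03), the gelatinase Mmp9 (10.15 against 5.72) and the stefin Stfa2l1 (8.34 against 3.0). The largest measured difference belonged to Il1f9, an interleukin-1 family cytokine (10.59 against 4.17). The median level of all probe sets was 4.03 to 4.20 in the 4 arrays, and the upper end of the central 95% of chemosensory receptor genes, taken here as a guide to background after the values were seen, was 5.38 to 6.09. Where the dimmer array lies in or below that range, here and in the comparisons that follow, the size of a difference and its rank are uncertain. Other genes among the 10 with the largest positive difference were Il23a (8.80 against 3.76), Trem1, an amplifier of myeloid activation (10.51 against 6.25), and the cystatin-like genes Csta3 (7.33 against 2.65) and Stfa1 (7.38 against 3.11), together with Mrgpra2a (9.25 against 4.99). Inflammatory mediators were higher as a list, with 9 of 17 measured members at least 2-fold higher and none that much lower; Cxcl3 differed by 3.39, Nlrp3 by 3.25 and Il1b by 2.78. Inflammatory monocyte genes were higher in 10 of 16 members, including Ly6c2 (3.87), Clec4e (3.46), Gsr (2.53) and Chil3 (2.42). Oxidative burst and granule genes (8 of 11, with Fpr2 at 3.43 and Cd14 at 2.13), immediate early genes (11 of 22, with Egr3 at 2.76 and Nfkbiz at 2.20) and hypoxia and glycolysis genes (6 of 12, with Slc16a3 at 2.90 and Egln3 at 2.84) were higher too. Of the hypoxia and glycolysis genes, 1 was at least 2-fold lower.

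Ly6C-low cells of WT livers carried transcripts of liver sinusoidal endothelium, resident macrophages and hepatocytes at higher levels than Ly6C-hi cells. All 17 sinusoidal endothelial markers were at least 2-fold higher in Ly6C-low, with a median hi minus low difference of -2.93. The largest measured was Clec4g, a lectin of sinusoidal endothelium (6.75 in Ly6C-hi, 10.63 in Ly6C-low), followed by Plpp1 (-3.80), the tight junction gene Cldn5 (-3.68) and the coagulation factor gene F8 (-3.68). Adgrl4 (-3.65), Cd59a (-3.61), Myct1 (-3.60), Adgrf5 (-3.48), Cyp4b1 (-3.48) and Cavin2 (-3.46) completed the 10 most Ly6C-low genes. Of 12 measured Kupffer cell genes, which mark resident liver macrophages, 6 were at least 2-fold higher in Ly6C-low, among them the complement receptor Vsig4 (-3.37), Cd5l (-2.14) and the folate receptor Folr2 (-2.07); Cdh5 (-3.24) and Clec1b (-2.11) are on that list and are also expressed by endothelium. Hepatocyte genes were higher in Ly6C-low in 7 of 13 members (Cyp2e1 -1.67, Fabp1 -1.53), and the albumin gene Alb read 10.15 in Ly6C-hi and 10.94 in Ly6C-low. The stellate cell genes Rgs5 (-2.93), Lrat (-2.49) and Dcn (-2.46) were higher in Ly6C-low as well, while the other 3 of 6 stellate and fibroblast members differed less than 2-fold. Repair macrophage genes went both ways, with Mrc1 (-2.08) and Retnla (-1.26) higher in Ly6C-low and Il1rn (2.60) and Vegfa (1.99) higher in Ly6C-hi.

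In all, 966 of 4762 genes were at least 2-fold higher in WT Ly6C-hi and 313 at least 2-fold higher in WT Ly6C-low. The median gene differed by 0.30, and after each array was centred on the median gene the counts were 645 and 494. Of the 21 fixed lists with at least 5 measured members, 6 had medians above and 6 below the central 95% of level-matched random lists. Relative to the median of all genes, 0.22 for the genes used with the lists, the largest list medians were 3.07 for neutrophil, 1.47 for oxidative burst and granule and 1.01 for inflammatory monocyte genes on the Ly6C-hi side, and -3.15 for sinusoidal endothelial, -1.66 for stellate and fibroblast, -1.31 for hepatocyte and -1.25 for Kupffer cell genes on the Ly6C-low side. Relative to that median, 10 of 13 hepatocyte and 5 of 19 complement and efferocytosis genes were at least 2-fold higher in Ly6C-low, against 7 and 2 as deposited. The repair macrophage median of -0.54 lay below the random lists, while the mean of its members was 0.02. Complement and efferocytosis genes lay below them at -0.26, with C1qa at -0.98 and Mertk at -0.91. With the mean of probe sets the stellate and fibroblast median lay within the random lists. In this and the other 3 pairwise comparisons, no list median outside the random lists changed sign when the arrays were centred, quantile normalised or corrected by lowess.

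**Figure D2:**
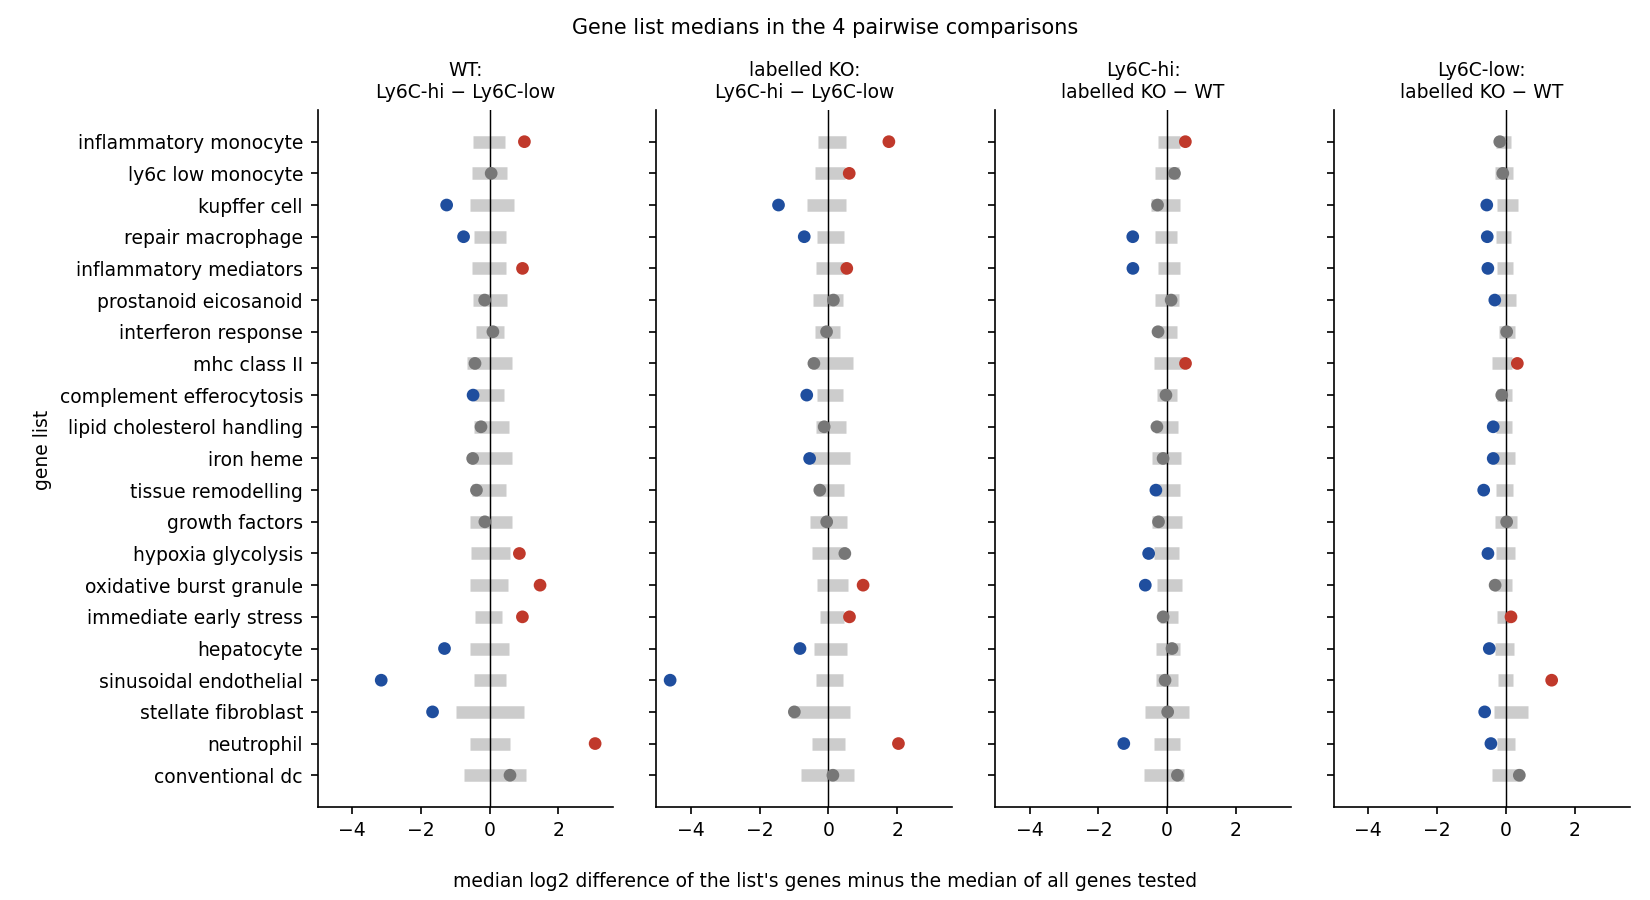
Median log2 difference of 21 gene lists minus the median of all genes tested (horizontal axis), in 4 pairwise comparisons; each point is 1 list, red above and blue below the central 95% of 10000 level-matched random lists of the same size (grey bars). Sinusoidal endothelial genes lie at -3.15 and -4.60 in Ly6C-hi minus Ly6C-low and at 1.33 in labelled KO minus WT of Ly6C-low, and neutrophil genes at 3.07, 2.04, -1.26 and -0.44 from left to right.

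Under the KO label, neutrophil and inflammatory monocyte genes were higher in Ly6C-hi, and hypoxia and glycolysis genes, with 1 of 12 at least 2-fold higher and 2 lower, lay within the random lists. Ly6c2 led the Ly6C-hi side (8.94 against 4.33), followed by Il1f9 (7.13 against 3.42), Ly6a2 (3.31) and the neutrophil genes S100a8 (9.62 against 6.69), Cxcr2 (2.83), S100a9 (2.70) and Mmp8 (2.65). Mcemp1 (2.39), Sirpb1c (2.38) and Trem1 (2.24) completed the first 10. Of the neutrophil markers, 13 of 15 were at least 2-fold higher in Ly6C-hi, with a median of 1.73 against 3.29 in WT. Inflammatory monocyte genes were higher in 10 of 16 members with a median of 1.45, including Chil3 (2.19), Clec4e (2.13) and Plac8 (2.10). Inflammatory mediators went both ways: Nlrp3 (2.08), Il1b (1.60), Ccl2 (1.03) and Il23a (1.02) were higher in Ly6C-hi, and Il1a (-2.87), Cxcl9 (-2.03) and Ccl5 (-1.1) were higher in Ly6C-low.

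The Ly6C-low side under the KO label was led by endothelial genes by size of the measured difference. F8 read 3.24 in Ly6C-hi and 9.74 in Ly6C-low, and the basement membrane gene Nid1 read 3.48 and 9.53 (-6.05). The hyaluronan receptor gene Stab2 (-5.98), Ptprb (-5.93), Adgrf5 (-5.85), Plpp3 (-5.84), Clec4g (-5.80), Dnase1l3 (-5.67), Cdh5 (-5.62) and the angiopoietin receptor gene Tek (-5.52) followed. All 17 sinusoidal endothelial markers were at least 2-fold higher in Ly6C-low, with a median hi minus low difference of -4.91. Kupffer cell genes were higher in Ly6C-low in 9 of 12 members (Slc40a1 -2.97, Vsig4 -2.75, Cd5l -2.05), hepatocyte genes in 9 of 13 (Fabp1 -2.68), repair macrophage genes in 7 of 14 (Mrc1 -3.59, Stab1 -2.91, Retnla -2.67) and complement and efferocytosis genes in 9 of 19 (Mertk -2.79, Pros1 -2.50). Stab1 and Mrc1 are also expressed by sinusoidal endothelium.

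Under the KO label 203 of 4541 genes were at least 2-fold higher in Ly6C-hi and 938 in Ly6C-low. The median gene differed by -0.37, and centred arrays gave 486 and 582. Relative to the median of all genes, -0.31 for the genes used with the lists, neutrophil genes stood at 2.04, inflammatory monocyte genes at 1.76, oxidative burst and granule genes at 1.01, sinusoidal endothelial genes at -4.60 and Kupffer cell genes at -1.45. Relative to that median, the members at least 2-fold higher in Ly6C-low were 3 of 13 for hepatocyte genes, 8 of 12 for Kupffer cell, 5 of 14 for repair macrophage and 7 of 19 for complement and efferocytosis genes, and those higher in Ly6C-hi were 13 of 16 for inflammatory monocyte and 14 of 15 for neutrophil genes. List medians were above the random lists for 6 lists and below them for 6. Among these, the mean of members brought inflammatory mediators within the random lists. The median of the non-classical (Ly6C-low) monocyte genes, 0.30, was among the 6 above, but the mean of its members was -0.24, with Fabp4 at -4.29, Cd36 at -2.85 and Nr4a1 at 1.47.

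The array labelled KO Ly6C-hi had lower levels of inflammatory and neutrophil genes than WT Ly6C-hi. Of 17 inflammatory mediators, 13 were at least 2-fold lower and none that much higher, with a median of -1.46. Il23a read 4.38 against 8.80 in WT, Cxcl3 read 6.02 against 10.20, Il1a 5.92 against 9.70 and Il1b 9.93 against 12.10. Of 15 neutrophil genes, 14 were at least 2-fold lower, with a median of -1.73: Il1r2 (-3.62), Stfa2l1 (-3.41), Mmp9 (-3.27) and G0s2 (-3.05). Ptgs2, which encodes the inducible cyclooxygenase upstream of mPGES-1, read 7.26 against 10.85. Csta3 (-4.71), Csf1, a macrophage growth factor (5.86 against 9.51), the cystine transporter gene Slc7a11 (-3.59), Il18rap (-3.47) and Il1f9 (-3.47) were among the 10 with the largest negative difference.

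Repair macrophage, oxidative burst, hypoxia and tissue remodelling genes also had lower medians in the array labelled KO Ly6C-hi, while Kupffer cell, complement, lipid and iron genes lay within the random lists (-0.28, -0.03, -0.30 and -0.12 relative to the median of all genes), though with lowess the Kupffer cell median lay below them (-0.60). Repair macrophage genes were at least 2-fold lower in 10 of 14 members (median -1.47), among them Il1rn (-2.82), Vegfa (-2.40), the lysosomal glycoprotein gene Gpnmb (7.07 against 9.44) and the fatty acid binding protein gene Fabp5 (9.10 against 10.96). Oxidative burst and granule genes were lower in 7 of 11 (Fpr2 -2.77, Cd14 -2.16), hypoxia and glycolysis genes in 6 of 12 (Egln3 -2.90, Slc16a3 -2.20) and tissue remodelling genes in 5 of 14 (Mmp9, Adam8 -1.80, Plaur -1.63). Of 16 inflammatory monocyte genes 1 was at least 2-fold higher and 3 that much lower. Ly6c2 (1.23), Ms4a4c (0.97), Plac8 (0.93) and Ccr2 (0.77) read higher under the KO label, while Thbs1 (-1.91), Clec4e (-1.84) and Gsr (-1.72) read lower. Class II antigen presentation genes had a median of 0.07, and on that list the costimulatory gene Cd80 read 6.75 against 10.05. The 10 genes with the largest positive difference were 9 olfactory or vomeronasal receptor genes and Csprs. They were Olfr1170 (8.45 against 5.60), Olfr988 (2.84), Olfr1302 (2.60), Olfr508 (2.31), Olfr1034 (2.31), Vmn1r36 (1.97), Olfr485 (1.93), Olfr824 (1.93) and Vmn1r127 (1.92). Csprs differed by 2.02 in its brightest probe set and by -0.75 in its dimmest.

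In Ly6C-hi, 103 of 4410 genes were at least 2-fold higher and 910 at least 2-fold lower under the KO label. The median gene differed by -0.53, and centred arrays gave 267 and 285. Relative to the median of all genes, -0.47 for the genes used with the lists, neutrophil genes stood at -1.26, repair macrophage genes at -1.0, inflammatory mediators at -0.99, oxidative burst and granule genes at -0.64, hypoxia and glycolysis genes at -0.54 and tissue remodelling genes at -0.33, and these 6 list medians lay below the random lists. Relative to that median, the members at least 2-fold lower were 8 of 17 inflammatory mediators, 9 of 15 neutrophil genes, 7 of 14 repair macrophage genes, 5 of 11 oxidative burst genes, 4 of 12 hypoxia genes and 4 of 14 tissue remodelling genes. Inflammatory monocyte and class II antigen presentation genes, both at 0.53, lay above the random lists. The means of their members as deposited, not relative to that median, were -0.10 and -0.40. By the mean, inflammatory monocyte genes stayed above the random lists (percentile 97.65) and class II genes lay within them (percentile 54.95). The class II median fell within the random lists under quantile normalisation (0.45) and lowess (0.30). Tissue remodelling genes lay within them with a log2 floor of 7, and hypoxia and glycolysis genes with the mean of probe sets.

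In Ly6C-low, endothelial genes were higher in the array labelled KO than in WT. Of 17 sinusoidal endothelial markers, 12 were at least 2-fold higher and none that much lower, with a median of 1.45; the largest were the signalling protein gene Bmp2 (7.60 against 5.20), Flt4 (2.08), Tek (2.06) and Stab2 (1.97). The 10 genes with the largest positive difference also held the semaphorin receptors Plxna2 (8.0 against 5.22) and Plxnd1 (2.23), the matrix genes Ltbp4 (2.66), Pxdn (2.45), Hspg2 (2.31) and Nid1 (2.27), the natriuretic peptide receptor gene Npr1 (2.62), the endothelial guidance receptor gene Robo4 (2.25) and the cadherin Fat4 (2.21). For Npr1 and Fat4 another probe set of the same gene differed by -0.34 and 0.00. Class II genes were higher in the median (0.45; H2-Ab1 0.66, H2-Eb1 0.62, H2-Aa 0.61), although none reached 2-fold. B cells express class II genes too, and of 3 B cell genes Ighm (1.5) and Cd79b (1.34) were at least 2-fold higher. The efferocytosis genes Pros1 (1.31), Stab1 (1.19) and Mfge8 (1.15) were at least 2-fold higher, with a median of 0.00 for their list (-0.12 relative to the median of all genes).

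In Ly6C-low, 3 of 12 Kupffer cell genes were at least 2-fold lower and 1 higher under the KO label, and 1 of 14 repair macrophage genes lower and 3 higher. Relative to the median of all genes, 4 Kupffer cell genes were that much lower and 1 higher, and 2 repair macrophage genes lower and 2 higher. Gpnmb had the largest negative difference (8.30 against 10.02), followed by Fabp7 (-1.49), the collagenase Mmp8 (-1.48), the platelet chemokine gene Ppbp (-1.45), Adam8 (-1.43), Lrp12 (-1.40), Olfr235 (-1.37), Il7r (-1.36), Vsig4 (5.85 against 7.15) and Vmn1r158 (-1.26). The Kupffer cell genes past 2-fold as deposited were Vsig4 (-1.29), Hmox1 (-1.18) and Folr2 (-1.03), lower, and Cdh5 (1.5), higher. Repair macrophage genes had a median of -0.42, with Gpnmb (-1.72), Il1rn (-0.88), Igf1 (-0.88) and Fabp5 (-0.82) lower and Tgfb1 (1.32), Stab1 (1.19) and Mrc1 (1.06) higher. Inflammatory mediators had a median of -0.40, with Cxcl1 (-1.02), Il1b (-0.99) and Ccl2 (-0.89) lower and Cxcl9 (1.16) higher. Hepatocyte genes had a median of -0.36, and Alb read 10.94 in both arrays.

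In Ly6C-low, 306 of 4444 genes were at least 2-fold higher and 36 at least 2-fold lower under the KO label. The median gene differed by 0.15, and centred arrays gave 228 and 75. Relative to the median of all genes, 0.12 for the genes used with the lists, 3 list medians lay above the random lists: sinusoidal endothelial (1.33), class II (0.33) and immediate early genes (0.15). Below them lay 11 lists: tissue remodelling (-0.65), stellate and fibroblast (-0.62), Kupffer cell (-0.56), repair macrophage (-0.54), inflammatory mediators (-0.52), hypoxia and glycolysis (-0.52), hepatocyte (-0.48), neutrophil (-0.44), lipid and cholesterol handling (-0.37), iron and heme (-0.37) and prostanoid and eicosanoid genes (-0.32). With a log2 floor of 7 the Kupffer cell median was 0.19 and the hepatocyte median -0.29, both within the random lists, and lipid genes lay within them too. The mean of members brought class II, immediate early, prostanoid and hypoxia genes within the random lists, a floor of 5 prostanoid and iron genes, and lowess and quantile normalisation iron genes.

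**Figure D3:**
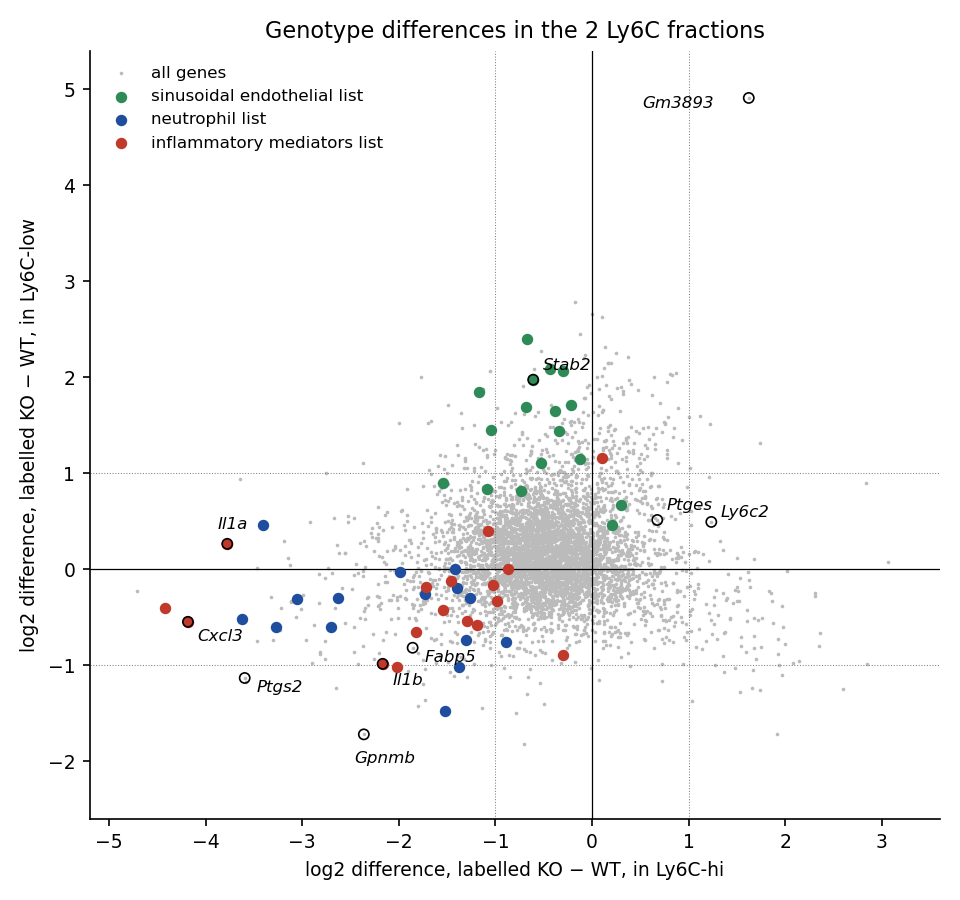
Log2 difference between the array labelled KO and WT in Ly6C-hi (horizontal axis) and Ly6C-low (vertical axis), 1 point per gene for 5306 genes, with 3 gene lists coloured and 10 genes ringed; dotted lines mark 2-fold. Endothelial genes lie high on the vertical axis (median 1.45) and neutrophil and inflammatory genes far left (medians -1.73 and -1.46), and across all genes r was 0.06.

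The prostanoid and eicosanoid genes, whose products make, degrade and sense prostaglandins and leukotrienes, differed by member. In WT, Ptgs2 (3.24) and the 5-lipoxygenase gene Alox5 (2.5) were higher in Ly6C-hi, and Hpgd (-2.69) and Slco2a1 (-2.36) were higher in Ly6C-low. Under the KO label Slco2a1 differed by -4.16 and Hpgd by -1.94, while Ptgs2 differed by 0.78 and Alox5 by 0.64. In Ly6C-hi, Ptgs2 (-3.60), Alox5 (-2.46), Alox15 (-1.33) and the prostaglandin E2 receptor gene Ptger2 (-1.1) were lower under the KO label. In Ly6C-low, Ptgs2 (-1.13) and Alox15 (-1.01) were lower and Slco2a1 (1.87) was higher. Slco2a1 went the same way as the sinusoidal endothelial genes. Their medians were -2.93 and -4.91 between fractions in WT and under the KO label, and 1.45 between the Ly6C-low arrays. Which cells Slco2a1 came from was not tested. The median of the list was 0.07 and -0.16 between fractions in WT and under the KO label and -0.35 between the Ly6C-hi arrays. All 3 lay within the random lists and changed sign relative to the median of all genes (-0.14, 0.15 and 0.12).

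Averaged over both genotype labels, the Ly6C fractions differed in 138 genes that were higher and 221 that were lower in Ly6C-hi (limma, additive model, adjusted p under 0.05, 5306 genes). The counts depended on the treatment of the arrays: 205 and 290 when centred, 304 and 320 with quantile normalisation, 390 and 364 with lowess, and 7 and 67 with no floor. The smallest adjusted p was 4.72e-26 as deposited, 0.00138 when centred and 0.0345 with no floor. The genes with the largest increase in Ly6C-hi were Il1f9 (5.07, SE 0.53, adjusted p = 1.64e-18), Ly6c2 (4.24, SE 0.54, adjusted p = 1.04e-12), Cxcr2 (3.88), Il1r2 (3.70) and Stfa2l1 (3.40). Those with the largest decrease were F8 (-5.09, SE 0.52, adjusted p = 5.01e-19), Clec4g (-4.84, SE 0.42, adjusted p = 4.72e-26), Stab2 (-4.69), Adgrf5 (-4.67) and Nid1 (-4.65). Of 17 sinusoidal endothelial genes 16 fell, and 17 when adjusted over the list alone. Of 15 neutrophil genes 11 rose (14 adjusted over the list alone), of 16 inflammatory monocyte genes 6 (12 adjusted over the list alone), of 17 inflammatory mediators 5 (8 adjusted over the list alone) and of 11 oxidative burst and granule genes 4 (7 adjusted over the list alone). Of 12 Kupffer cell genes Folr2, Vsig4, Cdh5 and Clec1b fell (5 adjusted over the list alone), the last pair also expressed by endothelium, of 14 repair macrophage genes 4 fell and Il1rn rose (5 and 1 adjusted over the list alone), and of 19 complement and efferocytosis genes 4 fell (7 adjusted over the list alone). With no floor and adjusted over the list alone, 0 complement and efferocytosis genes were called (8 unadjusted) and 1 oxidative burst and granule gene (7 unadjusted).

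By the same limma test of the fractions, of 22 immediate early genes Dusp1, Nfkbia and Zfp36 rose (5 adjusted over the list alone), of 12 hypoxia and glycolysis genes Slc16a3 and Slc2a1 rose (3 adjusted over the list alone), and of 14 tissue remodelling genes Mmp8, Mmp9 and Plaur rose and Timp3 fell (3 and 4 adjusted over the list alone). Adjusted over the list alone, 4 immediate early genes rose when centred, 9 with quantile normalisation and 12 with lowess, but 0 with no floor (7 unadjusted). Among prostanoid and eicosanoid genes Ptgs2, Alox5 and Alox5ap rose in Ly6C-hi while Hpgd, which encodes the prostaglandin-degrading dehydrogenase, and the prostaglandin transporter gene Slco2a1 fell, with the same counts adjusted over the list alone. Of 13 hepatocyte genes Alb and Fabp1 fell (5 adjusted over the list alone) and of 6 stellate and fibroblast genes Dcn and Rgs5 fell (3 adjusted over the list alone). Nr4a1 rose while Cd36 and Fabp4 fell among non-classical monocyte genes (2 and 2 adjusted over the list alone), Hpx fell among iron and heme genes (2 adjusted over the list alone), and Hgf among growth factors (1 adjusted over the list alone). Cd36 was the member of the lipid and cholesterol list that fell (1 adjusted over the list alone). With no floor and adjusted over the list alone, 0 iron and heme, 0 growth factor and 0 lipid and cholesterol genes were called. Of the hepatocyte genes only Fabp1 was called in that setting. Limma called 0 of 17 interferon response genes by either adjustment, and 0 of 8 class II genes over all genes with Cd80 higher when adjusted over the list alone. That Cd80 call was lost when centred, with lowess and with no floor, and stayed with quantile normalisation. Summed over the lists, calls adjusted over the list alone went from 62 higher and 57 lower to 42 and 43 with no floor. Over all genes 782 had an unadjusted p under 0.05. The test takes the genotype by fraction difference, pooled over genes of like level, as its noise. It cannot tell mice from arrays, since whether both fractions of a genotype came from the same mice or pools is not given in the sources used here.

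Averaged over both fractions, 16 genes fell and 1 rose under the KO label by the same test, but over all genes limma called 0 once the arrays were centred on the median gene (296 at an unadjusted p under 0.05). Quantile normalisation (260), lowess (378) and no floor (486) also left 0 calls, with the unadjusted counts given in brackets. With no effect, a share of 0.05 of the genes tested would have such a p by chance. The counts with quantile normalisation and no floor were below that share, and those when centred and with lowess were above it. In the average of both pairs, 235 genes differed at least 2-fold by genotype label and 281 by the split of the arrays that follows neither factor (219 and 165 when centred). The genes that fell were the inflammatory genes Il1a, Il1b, Il1f9, Cxcl3 and Ptgs2, the myeloid surface receptor genes Ccrl2, Clec4d, Cd80 and Il1r2, the macrophage genes Gpnmb, Fabp5 and Cd63, and Mmp9, Thbs1, Slc7a11 and H2-Q10. Ptgs2 fell by 2.36 (SE 0.46, adjusted p = 0.000807), while Slc7a11 fell by 2.38 (SE 0.51, adjusted p = 0.0028) and Cxcl3 fell by 2.37 (SE 0.50, adjusted p = 0.0018). Gpnmb fell by 2.04 (SE 0.42, adjusted p = 0.0018) and Il1b fell by 1.58 (SE 0.33, adjusted p = 0.0018). Much of this came from Ly6C-hi: labelled KO minus WT was -3.78 in Ly6C-hi and 0.26 in Ly6C-low for Il1a, -4.18 and -0.55 for Cxcl3 and -3.62 and -0.52 for Il1r2, against -2.36 and -1.72 for Gpnmb and -1.86 and -0.82 for Fabp5. The gene that rose was the predicted gene Gm3893, outside the naming rule and chosen after its values were seen (4.45 and 5.04 in WT Ly6C-hi and Ly6C-low, 6.08 and 9.95 under the KO label). Ptges had a mean difference of 0.59 (SE 0.57, adjusted p = 0.9999). The 5 largest mean differences in each direction included Csta3 (-2.47) and Il23a (-2.41), and on the positive side Olfr988 (1.87), Olfr1383 (1.53), Sema6a (1.46), Sema6d (1.42) and Enpep (1.42), none of which passed the test. Without the trend limma called Csta3 and Il23a lower, together with Cxcl3, Ptgs2 and Slc7a11, and with a log2 floor of 5 it called Il23a lower and Olfr988 higher.

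By list, the limma test of the genotype label called 3 of 17 inflammatory mediators lower (6 adjusted over the list alone), 2 of 15 neutrophil genes (8 adjusted over the list alone), 2 of 14 repair macrophage genes (6 adjusted over the list alone) and 1 of 14 tissue remodelling genes (5 adjusted over the list alone). A single call each fell on Thbs1 among inflammatory monocyte genes (2 adjusted over the list alone), Ptgs2 among prostanoid genes (2 adjusted over the list alone) and Cd80 among class II genes (1 adjusted over the list alone). Igf1, Vegfa and Csf1 among growth factors, Egln3 and Vegfa among hypoxia genes, and Cd14 and Fpr2 among oxidative burst genes were lower only when adjusted over the list alone. Limma called 0 genes by either adjustment on the sinusoidal endothelial, hepatocyte, Kupffer cell, interferon, complement, immediate early, lipid, iron, stellate, non-classical monocyte and dendritic cell lists. Of all 5306 genes, 164 had an unadjusted p under 0.05, a smaller share than the 0.05 that would by chance. When the arrays were centred, limma adjusted over the list alone called 8 of 15 neutrophil genes lower, with Retnlg in place of Csf3r. It called 4 of 14 repair macrophage genes lower, with Tgfb1 higher, but 0 of 17 inflammatory mediators, of which 8 had an unadjusted p under 0.05. Quantile normalisation gave 3 mediators called and lowess 5. Centring also left 0 calls among inflammatory monocyte and oxidative burst genes (4 unadjusted in each), and Csf1 was not called with centring, quantile normalisation or lowess. With no floor the calls over all lists went from 40 to 8, a gene on 2 lists counted in each: 6 neutrophil genes, Gpnmb and Il7r. This rerun on the lists was chosen after the values were seen.

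No residual degree of freedom is left to test whether the effect of the genotype label differed between the fractions. The difference of differences (Ly6C-hi minus Ly6C-low) was most negative for Csf1 (-4.59), Csta3 (-4.48), Il1a (-4.04), Il23a (-4.02) and Stfa2l1 (-3.87). It was most positive for Olfr1302 (3.85), Olfr1170 (3.84), Vmn1r158 (3.0), Olfr485 (2.93) and Vmn1r149 (2.90). Past 2-fold it was negative in 1697 and positive in 164 of 5306 genes, with a median of -0.67, and centred arrays gave 446 and 519. Across genes, the fraction differences of WT and of the KO label ran together (Pearson r = 0.64, Spearman rho = 0.53 over 5306 genes, which are not independent replicates), with 142 genes at least 2-fold higher in Ly6C-hi under both labels (42.0 if independent), 330 lower (74.0) and 38 opposite. The genotype differences of both fractions hardly did (r = 0.06, rho = 0.03), with 6 genes at least 2-fold higher under the KO label in both fractions (6.51 if independent), 18 lower (7.43) and 51 opposite. The 18 lower genes, named after their values were seen, included Gpnmb, Ptgs2, Slc7a11, Adam8, Clec4d, Thbs1, S100a8, Mmp8, Alox15 and the platelet genes Pf4 and Ppbp.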

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

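The tests of explanations in this part were all chosen only after the results they bear on were seen, while the comparisons of effects between groups follow rules set earlier. Each gene difference in the next paragraphs rests on 1 array per group and was not tested.

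The endothelial genes F8, Plpp3 and Ptprb had differences of opposite sign in both gates under the KO label, but the sign in Ly6C-hi is uncertain, because they read 4.59, 5.47 and 5.96 in WT and 3.24, 4.42 and 4.79 under the KO label there, near background, and the 17 sinusoidal endothelial genes together stood at -0.06 relative to the median gene in Ly6C-hi, within random lists. Labelled KO minus WT was -1.34 in Ly6C-hi and 1.47 in Ly6C-low for F8 (difference -2.81), -1.05 and 1.45 for Plpp3 (difference -2.50), and -1.17 and 1.84 for Ptprb (difference -3.02). After centring, the Ly6C-hi values were -0.88, -0.58 and -0.70. Csf1 and Il1a differed between gates in opposite directions under the genotype labels. Ly6C-hi minus Ly6C-low was 3.54 in WT and -1.05 under the KO label for Csf1 (difference 4.59), and 1.17 and -2.87 for Il1a (difference 4.04). After centring, Csf1 under the KO label was -0.74 and Il1a in WT was 0.96.

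Some chemosensory receptor genes, which encode odorant and pheromone receptors of sensory neurons, had differences of opposite sign too. They belong to the genes used as a guide to background, so these signs are uncertain. The genotype difference in Ly6C-hi exceeded that in Ly6C-low by 3.85 for Olfr1302, 2.40 for Olfr235, 2.93 for Olfr485, 2.90 for Vmn1r149 and 3.0 for Vmn1r158, with opposite signs in both gates. The gate difference in WT minus that under the KO label was -2.59 for Olfr1034, -3.84 for Olfr1170, -2.40 for Olfr235, -2.93 for Olfr485, -2.56 for Olfr508, -2.80 for Vmn1r127, -2.90 for Vmn1r149, -3.0 for Vmn1r158 and -2.35 for Vmn1r36. Outside the named genes, 8 probe sets with no listed gene were at least 2-fold higher and 27 at least 2-fold lower under the KO label in both gates, of 3150 at or above the floor.

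Inflammatory, neutrophil and repair macrophage genes were lower in the array labelled KO Ly6C-hi than in WT Ly6C-hi. That array showed signs of an altered signal: the smallest SD (1.69), the fewest genes at the floor (3066), 157 chemosensory receptor genes at least 2-fold higher than in WT and 6 lower, and ribosomal protein genes at 0.70. For the inflammatory mediators, a compression that depends on level is argued against as the whole cause, since their median stayed at -1.13 (interval -1.77 to -0.50, 17 genes) after lowess removed the trend with level. The list already lay below level-matched random lists as deposited, so the lowess value adds little to that comparison. Other changes of signal stay open for the mediators, and so does a smaller share of neutrophils, which was not tested for them. Whether that sample held a smaller share of neutrophils stays open. The neutrophil median was -1.26 relative to the median gene (interval -2.59 to -0.93, 15 genes), which restates the pattern, beside 0.53 for inflammatory monocyte genes. The members had a robust SD of 0.68 against a spread between 2 arrays of 0.50, and ran from -0.89 for S100a9 to -3.62 for Il1r2. The 0.50 came from the split of the arrays that follows neither genotype nor gate, not from the Ly6C-hi arrays alone. It holds any genotype by gate difference and is not replicate noise. Whether the members share 1 ratio therefore cannot be told, and no single ratio speaks for a smaller share. The abundant markers S100a8 and Il1r2 read 11 and 11.28 in WT and 9.62 and 7.66 under the KO label; the gate is named by Ly6C on macrophages, how neutrophils were excluded is not given in the sources used here, and 3 of the list's genes (Mmp8, Mmp9, Lcn2) stand on other lists. A smaller share of neutrophils stays open for the repair macrophage genes too, since their median of -1.0 (interval -1.53 to -0.31, 14 genes) restates the pattern, neutrophils also express members such as Il1rn and Vegfa, and Kupffer cell genes lay within random lists as deposited (-0.28) and below them with lowess (-0.60). A difference in the state or mix of monocytes and macrophages, or an effect of the genotype, stays open and untested with 1 array per group.

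Sinusoidal endothelial genes were higher in the Ly6C-low arrays, and more so under the KO label. Whether endothelial cells or their RNA in the Ly6C-low samples are the source stays open. All 17 of 17 markers were at least 2-fold higher in Ly6C-low under both labels, which restates the pattern, with median levels of 8.47 in WT and 9.37 under the KO label, and the most abundant, Clec4g and Ehd3, were at 10.63 and 10.35 in WT and 11.46 and 11.16 under the KO label. The markers' differences between the Ly6C-low arrays had a robust SD of 0.77, against a spread between 2 arrays of 0.50 from the split that follows neither factor. The spread of 0.50 holds any genotype by gate difference and is not replicate noise. Whether the markers share 1 ratio therefore cannot be told, and no single ratio speaks for 1 source of the difference between those arrays. The robust SD of the markers does not bear on which cells they came from in either array. The samples are named as macrophages, but how endothelial cells were excluded is not given in the sources used here. Fcgr2b, Lyve1 and Pecam1 on the list are also made by macrophages or other leukocytes. Between the Ly6C-low arrays, hepatocyte genes stood at -0.48 relative to the median gene (interval -0.73 to -0.13, 13 genes). Endothelial genes stood at 1.33 (interval 0.77 to 1.72). This argues against a lower share of macrophages that raised both alike. With a log2 floor of 7 the hepatocyte median, at -0.29 before centring, lay within random lists, and hepatocyte RNA need not come from cells in the sample. A lower share of macrophages beside more endothelial material stays open. Kupffer cell genes stood at -0.56, with 3 of 12 at least 2-fold lower as deposited and 1 higher. With a floor of 7 their median was 0.19 before centring. Whether the genotype changed the number of endothelial cells carried along, or their expression, stays open and untested.

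Ptges was higher, not lower, in both arrays labelled KO. Scatter of probe sets at this level stays open: 0.59% of 1521 genes of like level were as much higher under the KO label in both gates, but 5.00% and 18.5% were in Ly6C-hi and Ly6C-low singly, the count was chosen because both differences were positive, and limma gave a mean of 0.59 with an SE of 0.57 (adjusted p = 0.9999). Exchanged genotype labels cannot be told apart from a probe set outside the deleted part by the mean difference of 0.59, because no probe positions, replicates or second marker of genotype were at hand. Lowess left the Ly6C-low difference at 0.15 and the Ly6C-hi one at 1.25. An effect of the genotype on transcription of the remaining gene stays open and untested.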

How the results depend on the processing

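Of the counts and correlations that answer a comparison, 105 stayed within 1.5 times their value or within the spread and 85 moved; 533 list medians kept their place, 9 moved, 13 passed out of and 20 fell back into the random range and 5 changed sign; 276 named gene values stayed, 57 moved and 3 changed sign. In what follows, counts are given as higher then lower. Changes of floor and threshold alter how many genes are counted by construction; for the others the cause was not tested. With a log2 floor of 5, WT Ly6C-hi minus low had 525 lower, the KO label 313 higher, labelled KO minus WT 230 higher in Ly6C-hi and 80 lower in Ly6C-low, the difference of differences 444 higher, limma's gate effect 391 lower and its genotype effect 4 higher, with r of 0.50 between gate effects and -0.065 between genotype effects. With a floor of 7 the pairwise counts were 628 and 139, 130 and 496, 43 and 552, and 176 and 19, the difference of differences 55 and 924, limma's gate effect 119 lower and genotype effect 2 higher, and r 0.73 and 0.13. With no floor, 773 were lower in the WT gate comparison, 499 higher under the KO label, 512 higher in Ly6C-hi, 165 lower in Ly6C-low and 1463 higher in the difference of differences; limma called 7 and 67 genes for gate and 0 and 0 for genotype (486 at an unadjusted p under 0.05). Centring on the median gene gave 494 lower in WT, 486 and 582 under the KO label, 267 and 285 in Ly6C-hi, 75 lower in Ly6C-low, 519 and 446 for the difference of differences and 0 and 0 limma genotype calls (296 unadjusted). Lowess gave 544 and 514, 438 and 470, 264 and 253, 187 and 102, and 384 and 560, limma gate 390 and 364 and genotype 0 and 0 (378 unadjusted), and r 0.57 and -0.030. Quantile normalisation gave 629 and 529, 578 and 485, 279 and 271, 183 and 101, and 469 and 522, limma gate 304 higher and genotype 0 and 0 (260 unadjusted). At 1.5-fold the counts were 1716 and 618, 530 and 1736, 220 and 2018, 845 and 225, and 308 and 2868. Limma without trend called 5 genes lower by genotype. Being 2-fold the same way in both pairs gave 6 genes higher by genotype. Protein-coding genes only, chosen after seeing the data, gave 65 higher in Ly6C-hi and 104 higher in the difference of differences. The mean of members, in place of the median, turned repair macrophage genes in WT to 0.019, non-classical monocyte genes under the KO label to -0.24, and inflammatory monocyte and class II genes between the Ly6C-hi arrays to -0.10 and -0.40. Of these, the inflammatory monocyte genes still lay above the random lists by the mean. A floor of 7 turned the Kupffer cell median between the Ly6C-low arrays to 0.19. The dimmest probe set gave -0.75 for Csprs, 0.00 for Fat4 and -0.34 for Npr1. Of 46 list medians outside the random range, 46 stayed there when centred, 43 with lowess, 44 with quantile normalisation, 43 with a floor of 5, 39 of 44 with a floor of 7, 44 with the mean of probe sets and 37 with the mean of members, and 0 crossed to the other side. Signal close to background limits what the counts with a low floor can show. No paired analysis was possible because the labels give no replicate numbers that pair arrays beyond genotype and gate; the additive limma model already compares the gates within each genotype label.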

Other observations

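The lists below, except the 3 named as added, were fixed earlier, and the test around Ptges and the genes singled out here were chosen after the values were seen. Interferon response genes had medians of 0.31 and -0.36 between gates in WT and under the KO label, and -0.73 and 0.14 between labels in Ly6C-hi and Ly6C-low. Lipid and cholesterol genes had -0.03, -0.43, -0.76 and -0.25 in the same order, iron and heme genes -0.27, -0.85, -0.59 and -0.25, growth factors 0.08, -0.35, -0.72 and 0.14, non-classical monocyte genes 0.26, 0.30, -0.25 and 0.03, and conventional dendritic cell genes 0.81, -0.17, -0.17 and 0.51. The iron median under the KO label lay below random lists, and lowess, floors of 5 and 7 and the mean of members each brought it within them. Slc40a1, the iron exporter gene, read 6.92 in WT Ly6C-hi, 6.99 in WT Ly6C-low, 4.28 in labelled KO Ly6C-hi and 7.25 in labelled KO Ly6C-low.

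Few members of the other cell type lists were at or above the floor. The cell cycle list had 3 of 34 (Pcna, Mcm3, Mcm6), the cholangiocyte list 0 of 8 and the erythroid list 0 of 12. Gzma of the NK list read 7.50, 4.97, 5.27 and 5.45 in WT Ly6C-hi, WT Ly6C-low, labelled KO Ly6C-hi and labelled KO Ly6C-low, Siglecf of the eosinophil list 7.53, 4.69, 5.18 and 4.70, Kit of the mast cell list 5.11, 7.09, 4.32 and 8.72, Il7r of the T cell list 6.13, 6.50, 4.40 and 5.14, Ighm of the B cell list 8.55, 7.78, 8.74 and 9.29, and Tcf4 of the plasmacytoid dendritic cell list 6.28, 7.08, 6.63 and 7.79. Of 3 measured platelet genes, Pf4 and Ppbp were lower under the KO label in both gates. Their differences in Ly6C-hi and Ly6C-low were -1.75 and -1.19 for Pf4 and -1.14 and -1.45 for Ppbp. The remaining member was at least 2-fold higher in Ly6C-hi and differed less than 2-fold in Ly6C-low. Limma called Pf4 and Ppbp when adjusted over these 3 genes alone and neither over all genes.

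Over all 1425 chemosensory receptor genes, an added list, the median labelled KO minus WT was 0.32 in Ly6C-hi, with 157 genes at least 2-fold higher and 6 lower, and -0.14 in Ly6C-low, with 6 higher and 59 lower. Ly6C-hi minus Ly6C-low was -0.23 in WT and 0.22 under the KO label. Their median levels were 2.45, 2.77, 2.85 and 2.60 in WT Ly6C-hi, WT Ly6C-low, labelled KO Ly6C-hi and labelled KO Ly6C-low, and 6, 33, 42 and 16 of them reached the floor. Ribosomal protein genes, also added, stood at -0.61 between gates in WT, 0.23 under the KO label, 0.70 between the Ly6C-hi arrays and -0.16 between the Ly6C-low arrays relative to the median gene, and proteasome genes at -0.49, -0.11, 0.13 and -0.25.

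Passenger DNA of the strain in which the gene was targeted could alter genes beside Ptges. Of the 20 nearest genes, 0 differed at least 1.5-fold the same way in both gates, against 1.27% of all genes. This decides nothing, because 17 of the 20 had a mean level under 6 and so few were to be found by chance.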
